A study of Mus musculus with 24 samples.

How the data were processed

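Gene expression was measured on Affymetrix mouse Gene 1.0 ST arrays in mammary epithelial cells sorted from mice with a tamoxifen-inducible Cre recombinase under Lgr5 control, either carrying a mutant PIK3CA transgene (mutant) or not (control). Glands were taken 4 weeks after tamoxifen from pools of 2 to 3 estrus-synchronised mice per genotype, in 3 independent sortings. Cells without the leukocyte antigen CD45 were divided by CD24 and Sca1 into a basal gate (CD24 low, Sca1 negative) and luminal gates (CD24 high, Sca1 negative or positive), and by GFP, which the labels give as marking cells that express Lgr5, the transgene or both. RNA of 250 cells per sample was amplified before hybridisation. There were 24 arrays in 8 groups of 3.

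The deposited values are log2 expression values per probe set, 1 column per array. The labels name the software affy with no version or role, and do not state the background correction, normalization or summarization. The scale was taken from the values: they ran from 2.586 to 13.54, and the medians of the arrays lay between 4.386 and 4.554. Their standard deviations lay between 1.829 and 1.987. Of 34760 probe sets, 21640 had 1 gene symbol in the platform annotation, and 21553 of these matched a gene of the mouse reference annotation (GRCm38.p6) by Entrez identifier, with 0 symbols changed. The other 13120 probe sets, with several symbols or none, were left out of the gene tests and fitted apart. Where a gene had several probe sets, the one with the highest mean over all arrays was kept, which concerned 954 of the 19937 genes tested. No array was left out.

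The comparisons, gene lists, rule for named genes and most alternatives were fixed before the data were examined. A single limma fit (limma 3.58.1 in R 4.3.3) gave each of the 8 groups its own mean, with 16 residual degrees of freedom and moderated standard errors. The contrasts were 10 comparisons of group pairs and 3 differences of effects. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, two-sided, with the adjustment made within each contrast. Errors of differences are standard errors of the fit, and errors of levels are standard deviations of 3 arrays. The replicates are pools of mice from separate sortings, so the p-values measure whether a difference exceeds the spread between pools, taken as equal in the 8 groups. The number of arrays limits the precision.

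Genes named in the text follow a rule. It takes up to 8 genes each way with the largest log2 difference among called genes whose 3 arrays in one group all lie above the 3 in the other, without predicted genes, clones, receptors of smell and small RNAs. It adds up to 4 called members of each gene list with the smallest p, and always Pik3ca, Lgr5, Cd24a, Ly6a, Ptprc, Krt5, Krt14, Krt8, Krt18, Elf5, Esr1 and Pgr where measured. Ly6a, which encodes Sca1, had no probe set with 1 symbol and could not be read. For differences of effects the rule takes up to 5 genes each way with the smallest p. Other genes are said to have been chosen after their values were seen.

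The 22 gene lists were basal and myoepithelial genes, luminal keratins and junctions, luminal progenitor (alveolar) genes, hormone-sensing luminal genes, milk and secretory differentiation, Wnt targets and Lgr5-type stem cell genes, FOXO targets, sterol and fatty acid synthesis, glycolysis, the Notch pathway, the cell cycle, mesenchymal transition factors, interferon response, class I antigen presentation, immediate early and dissociation stress genes, ribosomal proteins, and markers of leukocytes, endothelium, fibroblasts, pericytes, adipocytes and erythroid cells. They were tested with camera at a preset correlation of 0.01 between genes, adjusted over all lists and the 10 group pairs, and again with a correlation estimated from the data. List tests against the control basal GFP-negative reference were adjusted over the 22 lists alone, so their adjusted p-values are not on the same scale. Counts of members adjusted over the list alone are given beside those over all genes. Some genes stand in more than one list, among them 5 of the 19 measured progenitor genes and 4 of the 19 measured milk genes.

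A lineage score per array was the mean log2 value of up to 200 luminal-high genes minus that of up to 200 basal-high genes, each differing by a log2 difference over 1 and with the smallest p. The genes for each comparison were chosen on arrays outside it. For basal comparisons these were both control luminal groups against the other control basal group. For luminal comparisons they were the other control luminal group against both control basal groups. The score was tested with a two-sided exact permutation test of 3 arrays against 3, whose smallest p is 0.1. The same gene sets were tested with camera, adjusted over these 8 tests.

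The code was tested on simulated data with 200 changed genes among 19937. In the 10 pair comparisons it recovered 28.4 to 44.8% of genes changed 1.5-fold, 55.2 to 76.1% of those changed 2-fold and 83.3 to 100% of those changed 4-fold, with at most 11 false calls. For the differences of effects the shares were 25.4 to 37.3%, 40.3 to 49.3% and 65.2 to 81.8%. Of 220 list tests on simulated values, the 3 planted shifts were called and 0 others. The simulated genes varied independently of each other and equally in all groups. The simulation therefore cannot show false list calls from correlated genes, or the effect of arrays of unequal quality.

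The alternatives were quantile normalization, leaving out genes with a mean under 4.1 (the 30th percentile), averaging or not collapsing probe sets, a fit of only the compared groups, the replicate number as a fixed or random block (statmod 1.5.0 for the random block), an intensity trend with robust spread, array weights, and leaving out each array of the compared groups in turn. For list tests they were an estimated correlation, fry, the block and quantile normalization, and for the lineage score 50 genes each way or the fixed lists. The control basal GFP-positive arrays were seen to stand apart, so the control basal GFP-negative arrays as the reference, and a fit without the control basal GFP-positive arrays, were added after seeing the data. Genes with a mean log2 value under 4.66 are called dim.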

Results

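The 24 arrays cover 8 sorted mammary populations with 3 pools each: basal GFP-negative, basal GFP-positive, luminal Sca1-negative and luminal Sca1-positive cells from control and from mutant mice. Basal cells were collected in both GFP states from both genotypes, though GFP can mark the transgene only in mutant mice. The luminal cells are GFP-positive in the mutant and GFP-negative in the control, so that genotype and GFP state go together there. Krt5 and Krt14, keratins of basal epithelium, stood at mean log2 levels of 11.53 to 11.92 and 11.22 to 11.59 in the 4 basal groups. Krt18, a luminal keratin, stood at 12.59 to 12.77 in the 4 luminal groups and 9.63 to 11.09 in the basal groups. Arrays of a group correlated with each other at 0.934 to 0.979 across genes. The control basal GFP-positive arrays stood apart in signal. Their log2 values had a mean standard deviation of 1.86 and their dim genes a mean of 4.08, against 1.97 and 3.94 in mutant basal GFP-positive arrays. They also had the lowest mean array weight (0.59 against 1.45).

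**Figure D1:**
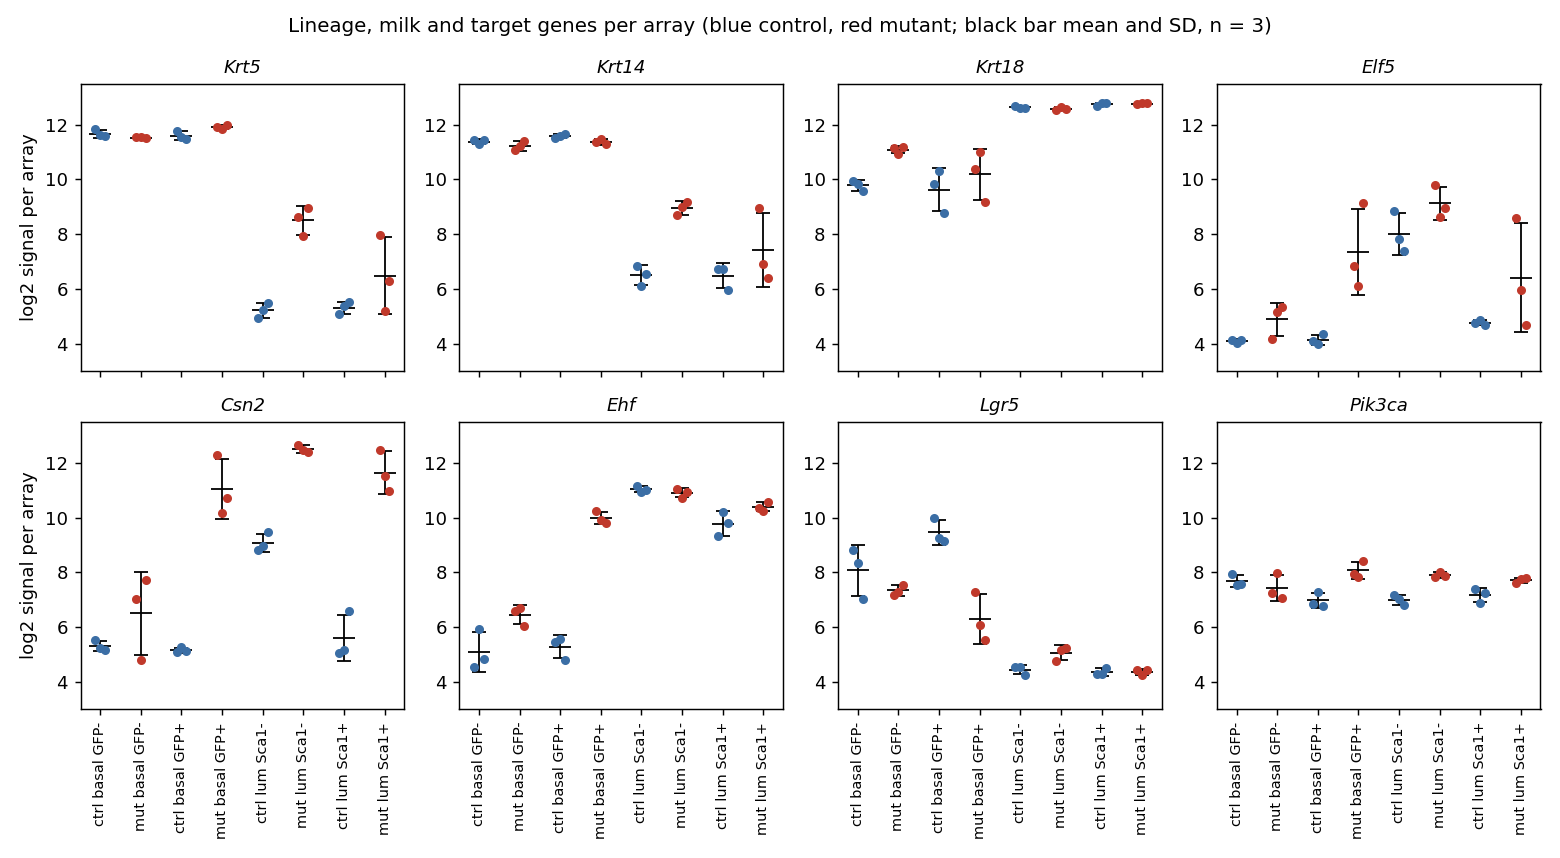
Log2 signal per array of 8 genes in the 8 sorted groups, with the mean and standard deviation of 3 arrays per group. Csn2 stands at 11.05 in mutant and 5.16 in control basal GFP-positive cells, Krt5 at 8.5 in mutant and 5.21 in control luminal Sca1-negative cells, and Lgr5 is highest in control basal GFP-positive cells (9.47).

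Whether Pik3ca signal differed with the genotype was read first, from the mouse Pik3ca probe set. The labels do not say whether that probe set also reads the transgene. Pik3ca encodes the catalytic p110-alpha subunit of phosphoinositide 3-kinase. It stood at 8.07 ± 0.31 in mutant and 6.98 ± 0.27 in control basal GFP-positive cells, a log2 difference of 1.09 (standard error 0.21, 3 arrays per group, adjusted p = 0.00435). In luminal Sca1-negative cells it stood at 7.90 ± 0.10 against 7.0 ± 0.19 (difference 0.90, adjusted p = 0.0593). Luminal Sca1-positive cells gave 7.72 ± 0.09 against 7.17 ± 0.26 (0.56, adjusted p = 0.424) and basal GFP-negative cells 7.43 ± 0.49 against 7.69 ± 0.22 (-0.26, adjusted p = 0.901). Within a genotype Pik3ca passed the test in none of the 6 pairs. GFP-positive against GFP-negative basal cells gave -0.71 in control (adjusted p = 0.109) and 0.64 in mutant (adjusted p = 0.156). Luminal Sca1-negative against basal GFP-positive cells gave 0.02 and -0.16, and Sca1-positive against Sca1-negative cells 0.16 and -0.18.

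The Pik3ca call in basal GFP-positive cells ended in a fit of only the compared groups (adjusted p = 0.0923) and against control basal GFP-negative cells (0.38, adjusted p = 0.394). The luminal Sca1-negative difference passed with dim genes left out (adjusted p = 0.0474) and with array weights (adjusted p = 0.0427). The difference between the basal fractions passed in control without GFP-positive replicate 2 (-0.86, adjusted p = 0.0363), and in mutant without GFP-negative replicate 2 (0.92, adjusted p = 0.0167). Against control basal GFP-negative cells, control luminal Sca1-negative cells had less Pik3ca (-0.68, adjusted p = 0.0493).

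The first question was what differs between mutant and control in basal GFP-positive cells, where GFP marks expression of Lgr5, the transgene or both. The casein Csn2 stood at 11.05 ± 1.10 against 5.16 ± 0.09 (log2 difference 5.90, standard error 0.62, adjusted p = 1.12e-05). Csn1s1 rose by 5.60 ± 0.66 and Wfdc18, of the whey acidic protein family, by 6.01 ± 0.79. Ehf, an epithelial ETS factor, rose by 4.70 ± 0.30 (adjusted p = 1.47e-08), the lipocalin Apod by 4.64 ± 0.34 (1.18e-07) and Elf5, an alveolar transcription factor, by 3.22 ± 0.77 (0.0144). The control levels of Csn1s1 (4.17), Apod (4.54) and Elf5 (4.14) are dim, under 4.66, so the sizes of these differences are not exact. The keratins of the basal layer did not pass the test (Krt5 0.32, adjusted p = 0.625; Krt14 -0.21, 0.754). Nor did the luminal Krt8 (0.34, 0.269) and Krt18 (0.55, 0.282). Among the lower genes were Grik3, a kainate receptor subunit (-4.26 ± 0.44, adjusted p = 1.06e-05), Cpxm2 (-2.93) and Serping1 (-4.43). Lgr5 itself, the R-spondin receptor whose locus drives the Cre, stood at 6.30 ± 0.90 against 9.47 ± 0.46 (-3.16 ± 0.39, adjusted p = 7.95e-05). Mutant basal GFP-negative cells had 7.34 ± 0.19. Control mice carry no transgene, so by the labels GFP marks Lgr5 there, while in mutant mice it can mark the transgene instead. The gate thus differs with the genotype, and a lower Lgr5 level cannot be told apart from this selection.

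Of 19 measured luminal progenitor genes 8 rose and 0 fell, and as many adjusted over the list alone. Csn3 (5.63), Mfge8 (3.39) and Wfdc18 had the smallest p. The list's median was 0.46 (adjusted p = 1.45e-06 by camera, and adjusted p = 0.134 with an estimated correlation). Against control GFP-negative cells that median was 1.01, with 6 higher and 0 lower (adjusted p = 8.6e-08, and adjusted p = 0.102 with an estimated correlation). Of 19 milk and secretory genes 8 rose and 1 fell (8 and 2 adjusted over the list alone), among them Csn2, Csn1s1 and Xdh, the xanthine dehydrogenase of milk fat globules (2.70). Their median was 0.32 (adjusted p = 1.83e-05, and adjusted p = 0.134 with an estimated correlation). The luminal keratin and junction list had 2 of 17 genes higher at either adjustment, Ehf with the smallest p (median 0.08; adjusted p = 0.0273, and adjusted p = 0.415 with an estimated correlation). Against control GFP-negative cells its median was 0.40, with 3 higher and 1 lower (adjusted p = 0.000784, and adjusted p = 0.192 with an estimated correlation).

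Glycolysis genes moved up with a median of 0.41, and the list passed also with an estimated correlation (adjusted p = 0.000169 and 0.0153). Against control GFP-negative cells the median was 0.25 (adjusted p = 0.0143, and adjusted p = 0.102 with an estimated correlation). Of its 13 genes 3 rose, the phosphofructokinase Pfkp (1.27) with the smallest p, and 6 rose and 1 fell adjusted over the list alone. Of 22 FOXO targets 4 rose, Sesn3 (3.41) and Cited2 (1.31) among them, and 2 fell, Igf1r (-2.03) among them (8 and 5 adjusted over the list alone). Their median was 0.29 (adjusted p = 0.0158, and adjusted p = 0.133 with an estimated correlation), and the list did not pass against control GFP-negative cells (0.0623). Sterol and fatty acid genes had 1 of 23 higher at either adjustment (median 0.34; adjusted p = 0.00131, and adjusted p = 0.257 with an estimated correlation). None of 31 cell cycle genes was called at either adjustment, with a median of 0.49 (adjusted p = 6.32e-05, and adjusted p = 0.483 with an estimated correlation). Against control GFP-negative cells that median was -0.24 (adjusted p = 0.852).

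Of 18 Wnt target and Lgr5-type stem cell genes 6 fell, Lgr5 and the Wnt inhibitor Wif1 (-2.01) among them, and Sox9 (0.83) rose (7 and 1 adjusted over the list alone; median -0.21; adjusted p = 0.0659). The GFP gate, which differs with the genotype, can add to falls of genes that go with Lgr5. Of 20 immediate early and dissociation stress genes 6 fell and 1 rose (10 and 1 adjusted over the list alone). Junb (-0.71), Hspa1a (-1.05) and Btg2 (-0.76) were among those that fell, and the median was -0.54 (adjusted p = 0.0129, and adjusted p = 0.426 with an estimated correlation). Against control GFP-negative cells it was -0.17 and the list did not pass (adjusted p = 0.363). In the Notch pathway the ligand Jag1 (2.75 ± 0.24, adjusted p = 1.23e-06) and Notch1 (1.47) were among 3 of 17 that rose, and 2 fell (3 and 3 adjusted over the list alone). The Notch median was -0.20 and its mean 0.15, with an adjusted p of 0.495 upward. Of 25 basal genes Nrg1, a ligand of ERBB receptors (3.30), Igfbp2 (2.25) and Actg2 (1.38) rose and Lmod1 (-2.14) fell (3 and 3 adjusted over the list alone; median 0.05; adjusted p = 0.0644).

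No marker of leukocytes rose in these mutant arrays: 2 of 17 fell, and 6 adjusted over the list alone (median -0.22; adjusted p = 0.0243, and adjusted p = 0.302 with an estimated correlation). The leukocyte list did not pass against control GFP-negative cells (median -0.10, adjusted p = 0.161). Ptprc, which encodes CD45, stood at 4.14 ± 0.04 against 4.35 ± 0.09 (adjusted p = 0.084). Markers of endothelium (median -0.18, 2 of 12 lower, adjusted p = 0.131) and pericytes (-0.16, 1 of 9 lower, 0.271) did not pass. Neither did those of adipocytes (-0.25, 2 of 7 lower, 0.611) and erythroid cells (-0.28, 0 of 2 called, 0.251). Fibroblast markers had a median of -0.19 and a mean of 0.20, with 2 of 12 higher, Dcn (4.30) with the smaller p (adjusted p = 0.968 upward). Hormone-sensing luminal genes (median -0.36, 1 of 14 lower, adjusted p = 0.363), mesenchymal transition factors (-0.15, 4 of 16 lower, 0.517) and class I antigen presentation (0.07, 0 of 8 called, 0.221) did not pass. Interferon response genes had a median of -0.07 and a mean of 0.04 (1 of 17 higher, 0.486 upward), and ribosomal proteins a median of -0.05 (0 of 14 called, 0.999 upward).

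In all, 946 genes were called higher and 1558 lower in mutant basal GFP-positive cells, 608 and 105 of them by at least 2-fold. The median of all genes was -0.10, that of dim genes -0.15 and that of bright genes 0.08, and 71.1% of the lower calls were dim genes. Against the control basal GFP-negative arrays, a reference chosen after seeing the data, 456 genes were higher and 185 lower, with 339 and 84 called in both. Of 60 named called genes 28 lost or turned their call there, among them Serping1 (-2.49, adjusted p = 0.0984), Dcn (1.79, 0.193), Igfbp2 (0.26, 0.664), Actg2 (-0.23, 0.696) and Pfkp (0.55, 0.307). Csn3 (2.24), Mfge8 (1.87), Lgr5 (-1.77), Junb (-0.36) and Hspa1a (-0.66) stayed called with smaller size, and Sox9 (1.35) with larger size.

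The count of 2504 was 1034, 1105 and 1236 without mutant replicates 1, 2 and 3, and 1388, 3979 and 1095 without control replicates 1, 2 and 3. It was 1213 with quantile normalization, 1515 with dim genes left out and 234 in a fit of only the compared groups. In that fit 32 of the named genes lost their call, among them Elf5 (adjusted p = 0.125), Lgr5 (0.0587), Cited2 (0.0561), Igf1r (0.052), Sox9 (0.0902), Wif1 (0.112), Btg2 (0.0951), Actg2 (0.105) and Lmod1 (0.0937). Elf5 also lost it without mutant replicate 3 (2.34, adjusted p = 0.0646). Csn2, Csn1s1, Wfdc18, Ehf, Apod, Xdh, Nrg1, Jag1, Notch1, Sesn3, Grik3 and Cpxm2 were called under every setting run.

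**Figure D2:**
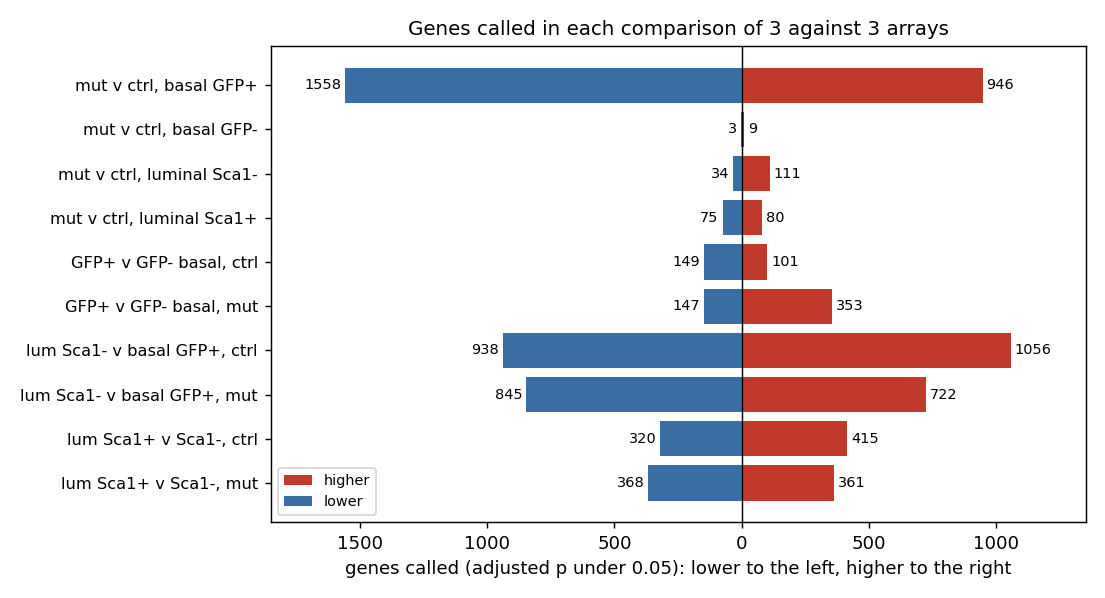
Number of genes called higher and lower (adjusted p under 0.05) in the 10 comparisons of group pairs, 3 arrays per group. The mutant effect in basal GFP-positive cells has 946 higher and 1558 lower genes, that in basal GFP-negative cells 9 and 3, and those in luminal Sca1-negative and Sca1-positive cells 111 and 34, and 80 and 75.

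The same question was put to the basal GFP-negative cells of the same mice. Apod stood at 8.73 ± 0.69 in mutant against 4.62 ± 0.52 in control (4.11 ± 0.34, adjusted p = 8.88e-06). That control level is dim, under 4.66, so the size of the difference is not exact. The 3 lower genes were the zinc finger gene Zfp354c (-1.66, adjusted p = 0.0403), Tceal5 (-1.28, 0.00492) and Zfp820 (-0.82, 0.0287). Krt5 (-0.14), Krt14 (-0.16), Lgr5 (-0.73, adjusted p = 0.802) and Krt18 (1.32, 0.366) did not pass. The luminal keratin and junction list moved up with 0 genes called, 4 adjusted over the list alone and a median of 0.32 (adjusted p = 3.54e-07, and adjusted p = 0.0614 with an estimated correlation). Milk genes had 0 called and 1 adjusted over the list alone (median 0.24; adjusted p = 0.00422, and adjusted p = 0.321 with an estimated correlation). Luminal progenitor genes had 0 called (median 0.29; adjusted p = 0.0185, and adjusted p = 0.454 with an estimated correlation).

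In total 9 genes were higher and 3 lower in mutant basal GFP-negative cells. In a limma fit of only the compared groups 0 were called, and Apod had an adjusted p of 0.644. The unadjusted p of that fit lay under 0.05 for 860 of 19937 genes, a share under 0.05 and so no more than chance alone gives. The count was 26 and 32 without mutant replicates 1 and 3, 7 with quantile normalization and 6 without the control basal GFP-positive arrays in the fit. Zfp354c lost its call in these last fits (adjusted p = 0.0528 and 0.0615), without control replicates 2 and 3 (0.115 and 0.103) and without mutant replicates 1 and 2 (0.103 and 0.0799). Zfp820 lost it without mutant replicate 2 (0.0747) and without the control basal GFP-positive arrays (0.0502).

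In luminal Sca1-negative cells, the gate of luminal progenitors, the mutant cells had more of genes typical of basal cells. Krt5 stood at 8.5 ± 0.52 against 5.21 ± 0.27 (3.29 ± 0.43, adjusted p = 0.000572) and Krt14 at 8.96 ± 0.25 against 6.50 ± 0.36 (2.46 ± 0.42, 0.00571). Both stayed below their basal levels, while Krt8 (-0.11, 0.903) and Krt18 (-0.04, 0.987) did not pass. Saa1, a serum amyloid A gene, rose most, by 6.35 ± 0.91 (adjusted p = 0.00127), followed by the milk protein Wap (5.90 ± 0.99, 0.0051) and Saa2 (4.91 ± 0.86, 0.00749). Csn2 rose by 3.44 ± 0.62 (0.00816), from 9.07 to 12.51, and the matrix protein Sparc by 3.64 ± 0.51. Amtn, which encodes amelotin, rose by 4.82 ± 0.30 (1.32e-07) and Igfbp3 by 4.38. Prom1, a marker of hormone-sensing luminal cells, fell by 2.17 (adjusted p = 0.00296), and Dcn (-3.29, 0.0284) and Mdga2 (-3.18, 5.3e-05) were lowest. Pgr (-2.03, 0.132), Esr1 (-0.66, 0.43) and Elf5 (1.12, 0.645) did not pass.

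Of 25 basal genes 5 rose and 0 fell, with Krt5, Sparc, Nrg1 (2.75) and Krt17 (2.15) having the smallest p, and 13 rose adjusted over the list alone. Their median was 0.62 (adjusted p = 5.1e-15, and 0.00726 with an estimated correlation). Milk genes had 3 of 19 higher, Wap, Csn2 and Lao1 (2.62), and 9 adjusted over the list alone (median 0.81; adjusted p = 1.59e-08, and 0.0449 with an estimated correlation). The hormone-sensing list had Prom1 lower of 14, and 5 adjusted over the list alone (median -0.64; adjusted p = 6.12e-06, and 0.0153 with an estimated correlation). Glycolysis had 2 of 13 higher, Ldha (1.30) and Aldoa (0.76), and 4 adjusted over the list alone (median 0.29; adjusted p = 0.00133, and 0.0358 with an estimated correlation). Luminal progenitor genes had Wap higher, and 3 higher and 1 lower adjusted over the list alone (median 0.26; adjusted p = 0.00027, and adjusted p = 0.269 with an estimated correlation). Sterol genes had 0 called (median 0.17; adjusted p = 0.0452, and adjusted p = 0.459 with an estimated correlation). Beside the basal genes, mesenchymal factors had 2 of 16 higher, with a median of -0.02 and a mean of 0.37 (adjusted p = 0.0782 upward). Of the leukocyte markers 1 of 17 was higher, and Ptprc stood at 4.06 ± 0.08 against 4.31 ± 0.14 (adjusted p = 0.226).

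In total 111 genes were higher and 34 lower in mutant luminal Sca1-negative cells, and a fit of only the compared groups called 34 genes. In that fit 19 of 29 named genes lost their call, among them Wap (adjusted p = 0.0564), Saa2 (0.0531), Nrg1 (0.118), Krt17 (0.0651), Lao1 (0.125), Prom1 (0.194), Mdga2 (0.139), Ldha (0.0519) and Aldoa (0.119). Mdga2 stood at -2.01 with probe sets averaged, and Dcn lost its call without any 1 of the 6 arrays (adjusted p 0.0539 to 0.124). Ldha lost it without control replicates 1 and 2 (0.0666, 0.0932) and mutant replicates 1 and 3 (0.113, 0.0655). Aldoa lost it without control replicates 1 and 2 (0.118, 0.0896) and mutant replicates 1 and 2 (0.143, 0.0824), and Pgr passed without mutant replicate 3 (-2.68, 0.0314).

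In luminal Sca1-positive cells, the gate of hormone-sensing cells, alveolar and milk genes were higher in the mutant. Csn2 rose by 6.05 ± 0.62 (adjusted p = 1.55e-05), Csn1s1 by 5.62 ± 0.66 (7.55e-05) and Apod by 5.62 ± 0.34 (1.77e-08). The cytokine gene Il17b (3.59 ± 0.23) and the matrix glycoprotein Thbs1 (3.50 ± 0.21) rose as well. Lower were Mdga2 (-5.32 ± 0.34, adjusted p = 3.03e-08), Tph1, the rate-limiting enzyme of serotonin synthesis outside neurons (-5.06 ± 0.65, 0.000257), and Ctsr (-4.09 ± 0.27). The receptor genes Esr1 (-0.12, adjusted p = 1) and Pgr (-0.88, 0.833) did not pass, nor did Krt8 (-0.07) and Krt18 (0.01). The same holds for Elf5 (1.63, 0.638), Krt5 (1.16, 0.389) and Krt14 (0.95, 0.57).

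Of 19 luminal progenitor genes 3 rose, Lcn2 (2.92 ± 0.26, adjusted p = 3e-06), Aldh1a3 (2.57) and Trf (2.56), and 11 adjusted over the list alone. Their median was 1.5 (adjusted p = 3.29e-18, and 0.00726 with an estimated correlation). Milk genes had Csn2 and Csn1s1 higher of 19, and 10 adjusted over the list alone (median 0.98; adjusted p = 6.86e-15, and 0.00726 with an estimated correlation). Interferon response genes had Usp18 (-1.63, adjusted p = 0.00306) and Bst2 (-1.64, 0.0123) lower of 17 (median -0.09; adjusted p = 0.0329, and adjusted p = 0.144 with an estimated correlation). Basal genes had 0 called and 3 adjusted over the list alone (median 0.24; adjusted p = 0.00131, and adjusted p = 0.269 with an estimated correlation). Cell cycle genes had 0 called (median 0.45; adjusted p = 3.57e-05, and adjusted p = 0.473 with an estimated correlation). Wnt genes had 1 of 18 higher (median 0.09; adjusted p = 0.0314, and adjusted p = 0.0858 with an estimated correlation), and ribosomal proteins 0 called (-0.07; 0.0314, and adjusted p = 0.364 with an estimated correlation). Replicate 1 of the mutant stood apart from replicates 2 and 3 in Krt5 (7.98, against 5.18 and 6.28) and Elf5 (8.58, against 5.96 and 4.67). It did so too in Acta2 (8.04, against 4.79 and 5.36), a gene chosen after its values were seen. Replicate 1 was also highest in Csn2 (12.48, against 11.51 and 10.96) and in Wap (10.96, against 8.83 and 5.64), the latter chosen likewise. Over the mutant arrays the mean of the progenitor list ran from 7.57 to 9.04 (control 6.68 to 6.82). That of the milk list ran from 6.14 to 7.65 (control 4.96 to 5.1). Whether Sca1-negative cells passed into this gate was not tested.

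In total 80 genes were higher and 75 lower in mutant luminal Sca1-positive cells, and 103 in all without control replicate 3. A fit of only the compared groups called 8. There 23 of 27 named genes lost their call, among them Csn2 (adjusted p = 0.0632), Csn1s1 (0.109), Lcn2 (0.172), Aldh1a3 (0.0651), Tph1 (0.0802), Ctsr (0.0603) and Usp18 (0.349). Apod, Il17b, Thbs1 and Mdga2 kept theirs. Trf lost its call there (0.188), with the replicate block (0.0503), without control replicates 1 and 3 (0.132, 0.123) and without mutant replicates 1 and 2 (0.164, 0.0771). Bst2 lost it there (0.141), without control replicate 1 (0.0735) and without mutant replicate 2 (0.0715).

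**Figure D3:**
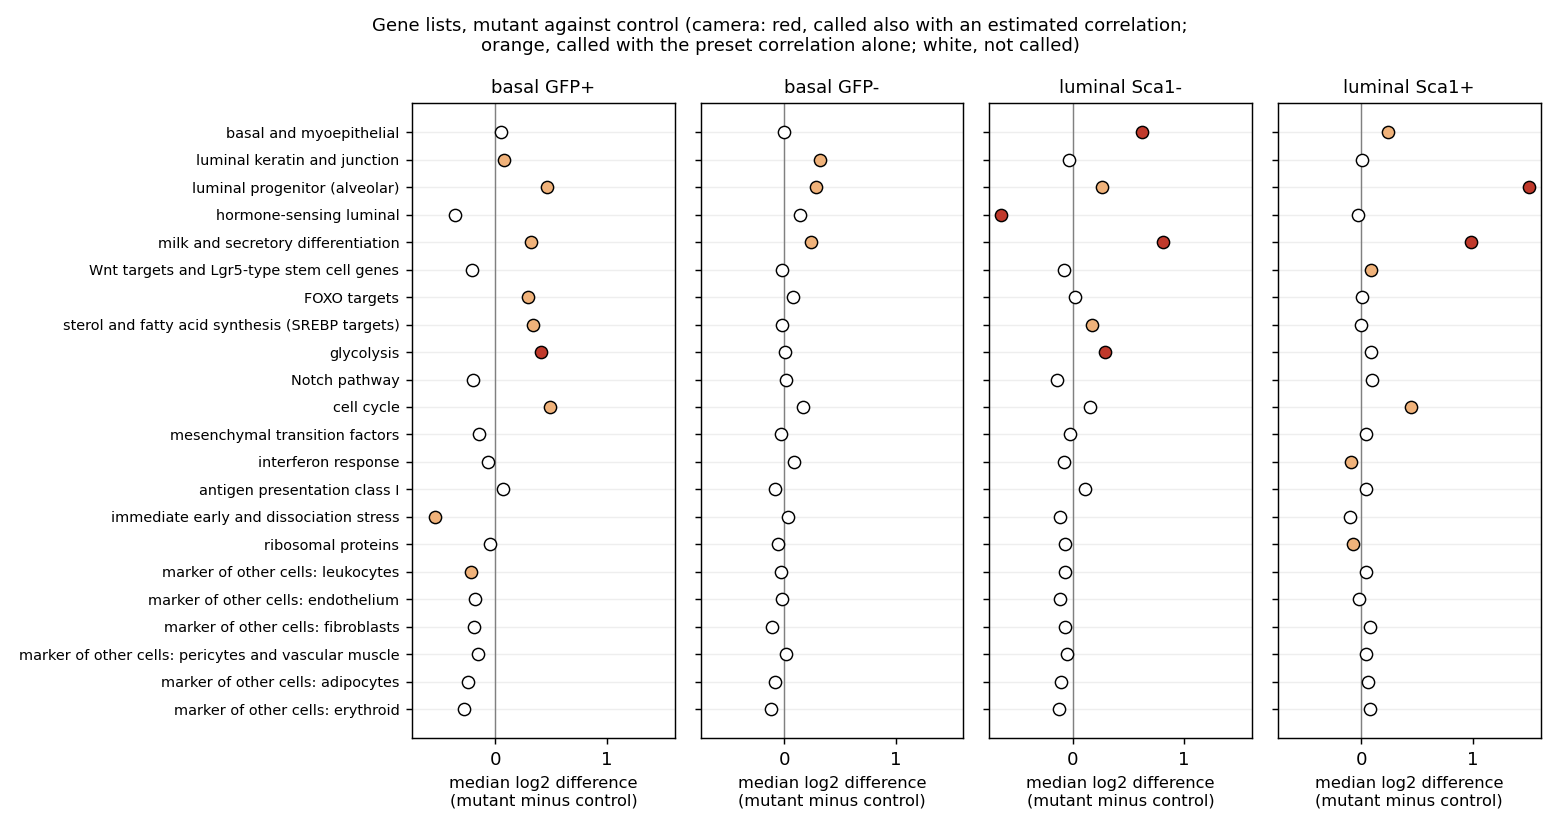
Median log2 difference between mutant and control of the 22 gene lists in the 4 sorted populations, with lists called by camera also with an estimated correlation in red, with the preset correlation alone in orange and others in white. Luminal progenitor genes have medians of 0.46, 0.29, 0.26 and 1.5 in basal GFP-positive, basal GFP-negative, luminal Sca1-negative and luminal Sca1-positive cells, and basal genes one of 0.62 in luminal Sca1-negative cells.

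Whether the mutant effects involve the same genes was asked of the 3 GFP-positive populations. Genes called higher in all of them were Apod, Csn2, Il17b (0.96, 3.10 and 3.59 in basal, Sca1-negative and Sca1-positive cells) and Lgals7 (1.76, 1.68 and 2.36). These are 4 genes where chance overlap gives 0.021, and 0 genes were lower in all (0.01 by chance). The luminal populations shared 10 higher genes (0.445 by chance) and 15 lower ones (0.128 by chance). Basal GFP-positive and luminal Sca1-negative cells shared 33 higher genes (5.27 by chance) and 1 lower (2.66 by chance), and basal GFP-positive and luminal Sca1-positive cells 22 (3.8 by chance) and 0 (5.86 by chance). These comparisons have no array in common, but populations can share a sorting, and all use the same spread per gene from the single fit. Either can add to an overlap, since the chance values take the calls as independent. RNA carried between gates can add to it as well. The same limits of the chance values hold for the overlaps between genotypes below. Lgals7 was chosen after its values were seen.

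How far the mutant cells moved between the lineages was read from a score of luminal-high minus basal-high genes. In luminal Sca1-negative cells the score was 0.15 ± 0.17 in the mutant and 1.08 ± 0.17 in the control (-0.93, two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). There the basal-high genes had a median of 0.40, with 17 called higher and 0 lower (adjusted p = 2.66e-22, and 0.00791 with an estimated correlation). The luminal-high genes had a median of -0.21, with 2 higher and 19 lower (adjusted p = 3.01e-05, and adjusted p = 0.0978 with an estimated correlation). They were chosen on control Sca1-positive against control basal cells and include genes of hormone-sensing cells such as Prom1. Control Sca1-positive arrays scored 3.16 to 3.31 on this score, and control Sca1-negative arrays 0.91 to 1.25. The fall thus cannot be read as a loss of luminal genes in general. The fixed luminal keratin and junction list had means of 10.12 ± 0.14 in the mutant and 10.1 ± 0.05 in the control. In basal GFP-positive cells the score was -1.62 ± 0.28 against -2.07 ± 0.28 (0.45, exact p = 0.2). Luminal-high genes there had a median of 0.37, with 44 higher and 3 lower (adjusted p = 3.05e-15, and 0.0142 with an estimated correlation). Basal-high genes had a median of 0.06, with 33 higher and 35 lower (adjusted p = 0.00924, and adjusted p = 0.272 with an estimated correlation). Basal GFP-negative cells had scores of -2.36 ± 0.09 against -2.61 ± 0.27 (0.25, exact p = 0.1; 0.094 without control replicate 1), and luminal-high genes a median of 0.14 (adjusted p = 5.17e-10, and 0.0142 with an estimated correlation). Luminal Sca1-positive cells had 2.04 ± 0.15 against 2.10 ± 0.13 (-0.06, exact p = 0.8), and basal-high genes a median of 0.13 (adjusted p = 5.76e-06, and adjusted p = 0.0824 with an estimated correlation). Their luminal-high genes had one of 0.08, with 9 higher and 10 lower (adjusted p = 0.0344, and adjusted p = 0.347 with an estimated correlation). Each population's score uses other genes, so the scores do not compare between populations. With the genes of the basal GFP-positive comparison, mutant Sca1-positive arrays scored 2.96 to 3.6 and control ones 3.9 to 3.97. Those genes were chosen partly on these control arrays. With the fixed lists in place of the chosen genes the difference was 0.157 in basal GFP-positive, 0.535 in basal GFP-negative and -0.26 in luminal Sca1-positive cells. With 50 genes each way it was -1.76 in luminal Sca1-negative cells.

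The next question was what marks GFP-positive among basal cells. In control mice Lgr5 stood at 9.47 ± 0.46 in GFP-positive and 8.07 ± 0.92 in GFP-negative cells (1.40 ± 0.39, adjusted p = 0.0898; 0.88 without GFP-negative replicate 3). Peg3, an imprinted zinc finger gene, was higher in the GFP-positive cells (2.18 ± 0.31, adjusted p = 0.00511). Csn3 (-3.39 ± 0.51, 0.00713), Ankrd1 (-3.27 ± 0.56, 0.0115), Igfbp2 (-1.98), the smooth muscle actin Actg2 (-1.61) and the luminal keratin Krt19 (-2.07) were lower. Krt5 (-0.08), Krt14 (0.21), Krt8 (0.06) and Krt18 (-0.14) did not pass. Cell cycle genes had a median of -0.74 with 0 called, and 1 lower adjusted over the list alone (adjusted p = 4.58e-08, and adjusted p = 0.359 with an estimated correlation). Immediate early genes had a median of 0.32 (adjusted p = 0.00238, and adjusted p = 0.334 with an estimated correlation). Basal genes had one of -0.21 with Igfbp2 and Actg2 lower (adjusted p = 0.00299, and adjusted p = 0.309 with an estimated correlation). The lists of ribosomal proteins (median -0.09), glycolysis (-0.12), mesenchymal factors (0.13) and pericytes (0.14) passed with the preset correlation (adjusted p = 0.000611, 0.049, 0.049 and 0.0329). With an estimated correlation they did not (adjusted p = 0.161, 0.173, 0.331 and 0.161).

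In total 101 genes were higher and 149 lower in control GFP-positive basal cells, 16 and 110 of them by at least 2-fold. Dim genes made up 52 of the higher and 11 of the lower calls. The GFP-positive arrays are those that stand apart, so their brighter dim genes can add to the higher calls. A limma fit of only the compared groups called 0, with 1690 genes at an unadjusted p under 0.05. The count was 32 with array weights, where Krt19 was lost (adjusted p = 0.0682). It was 104 and 132 without GFP-negative replicates 1 and 2, 1126 without GFP-positive replicate 2 and 166 without GFP-positive replicate 3.

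In mutant mice Saa1 (4.85 ± 0.91, adjusted p = 0.00534), the cytokine gene Il24 (4.77 ± 0.64) and Csn2 (4.54 ± 0.62) were the highest in basal GFP-positive against GFP-negative cells. The carbonic anhydrase Car12 (4.29 ± 0.31, adjusted p = 8.92e-08), Fndc1 (4.25 ± 0.19, 1.44e-10), the alarmin Il33 (4.20 ± 0.41) and the adhesion molecule Vcam1 (3.99 ± 0.55) followed. Notch1 (2.13), Jag1 (2.31) and Sox9 (1.35) rose with them, and Ankrd1 (-3.77), Grik3 (-3.66), the smooth muscle gene Tagln (-1.26) and Wif1 (-2.63) were lower. Lgr5 did not pass (6.30 against 7.34, -1.04, adjusted p = 0.249). It passed without GFP-positive replicate 1 (-1.53, 0.0419) and stood at -0.65 without GFP-positive replicate 3. Luminal progenitor genes had 2 of 19 higher, Tspan8 (3.46) with the smallest p, and 7 adjusted over the list alone (median 0.72; adjusted p = 6.67e-05, and adjusted p = 0.213 with an estimated correlation). Milk genes had Csn2 and Xdh (2.89) higher, and 8 higher and 1 lower adjusted over the list alone (median 0.41; adjusted p = 9.97e-05, and adjusted p = 0.166 with an estimated correlation). Glycolysis had the glucose transporter Slc2a1 (1.44) higher (median 0.25; adjusted p = 0.0185, and adjusted p = 0.114 with an estimated correlation). Ribosomal proteins had a median of -0.09 (adjusted p = 0.0109, and adjusted p = 0.306 with an estimated correlation).

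In total 353 genes were higher and 147 lower in mutant GFP-positive basal cells. The count was 321 and 314 without GFP-positive replicates 1 and 2 and 788 with array weights. A fit of only the compared groups called 191 and lost 23 of 43 named genes, among them Saa1 (adjusted p = 0.0564), Il24 (0.0816), Csn2 (0.122), Ankrd1 (0.181), Grik3 (0.0996), Wif1 (0.12), Tagln (0.0757) and Slc2a1 (0.122). The genotypes shared 9 higher genes (1.79 by chance) and 14 lower genes (1.1 by chance) between GFP-positive and GFP-negative basal cells.

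The lineages were compared within each genotype, luminal Sca1-negative against basal GFP-positive cells. In control mice the luminal cells had more Ceacam1 (6.84 ± 0.55, adjusted p = 1.15e-07), Wfdc18 (6.73), Gpx3 (6.07) and Ehf (5.74 ± 0.30, 2.56e-10). The receptor kinase Kit (4.73), Krt18 (2.99 ± 0.34) and Krt8 (1.91 ± 0.21) were higher too. Postn (-7.30 ± 0.46, adjusted p = 3.94e-09), the contractile genes Cnn1 (-6.87), Acta2 (-6.69) and Myh11 (-6.26), Krt5 (-6.38 ± 0.43), Krt14 (-5.09 ± 0.42) and Lgr5 (-5.02 ± 0.39) were lower. Of 25 basal genes 24 were lower, and 25 adjusted over the list alone (median -4.09; adjusted p = 2.86e-47, and 7.45e-05 with an estimated correlation). Of 17 luminal keratin and junction genes 14 were higher (median 2.23; adjusted p = 1.6e-20, and 0.00306 with an estimated correlation). Luminal progenitor genes had 12 higher and 1 lower of 19 (median 3.09; adjusted p = 5.48e-12, and 0.0317 with an estimated correlation), and hormone-sensing genes 6 higher and 1 lower of 14 (0.98; 0.000125, and 0.0403). Wnt genes had 6 of 18 lower, Lgr4 (-3.47) among them (median -0.38; adjusted p = 7.53e-06, and 0.00306 with an estimated correlation). Mesenchymal factors had 6 of 16 lower, among them Snai2 (-4.09) and Vim (-4.47), with a median of -0.32 (adjusted p = 7.33e-08, and 0.0101 with an estimated correlation). Milk genes had 10 higher (median 1.44; adjusted p = 3.84e-07, and adjusted p = 0.0735 with an estimated correlation). Immediate early genes had 10 lower and 1 higher of 20, among them Nr4a1 (-2.32), with a median of -0.50 (adjusted p = 5.85e-05, and adjusted p = 0.205 with an estimated correlation).

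In mutant mice the same comparison gave Amtn (6.11 ± 0.30, adjusted p = 2.41e-10), the haptoglobin gene Hp (5.66) and Ltf, which encodes lactoferrin (5.01), higher in the luminal cells. Myl9 (-5.73), Antxr1 (-5.57) and Cnn1 (-5.48) were lower, with Krt5 (-3.42 ± 0.43) and Krt14 (-2.42 ± 0.42), and Krt18 (2.41) and Krt8 (1.45) were higher. Lgr5 did not pass (-1.24, adjusted p = 0.0653). It passed with dim genes left out (0.0464), with array weights (0.0204) and without basal replicate 3 (-1.63, 0.0199), and stood at -0.75 without basal replicate 1. Of 25 basal genes 23 were lower, and 24 adjusted over the list alone (median -3.35; adjusted p = 3.61e-51, and 7.45e-05 with an estimated correlation). Of 17 luminal keratin and junction genes 13 were higher, and 14 adjusted over the list alone (median 1.45; adjusted p = 7.88e-18, and 0.00434 with an estimated correlation). Of 18 Wnt genes 2 were lower, Lgr4 (-2.58) and Sox9 (-0.98), and 9 adjusted over the list alone (median -0.28; adjusted p = 0.00027, and 0.00726 with an estimated correlation). Luminal progenitor genes had 8 higher (median 1.10; adjusted p = 8.59e-08, and adjusted p = 0.0897 with an estimated correlation) and milk genes 7 (1.45; 1.98e-06, and adjusted p = 0.0911 with an estimated correlation).

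In total 1056 genes were higher and 938 lower in control luminal cells, and 722 and 845 in mutant ones. The genotypes shared 370 higher genes (38.2 by chance) and 412 lower genes (39.8 by chance), with no array in common. A fit of only the compared groups called 765 genes in control, where 20 of 72 named genes lost their call, and 10 lost or turned theirs against the control GFP-negative basal cells. Krt5, Krt14, Krt18, Ehf and Kit in control, and Krt5, Krt14, Krt18, Amtn and Hp in mutant cells, were called in every setting run.

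The last question was what separates Sca1-positive from Sca1-negative luminal cells. In control mice the Sca1-positive cells had more Plac8 (3.94 ± 0.46, adjusted p = 4.76e-05), Il18r1 (3.49 ± 0.30), Foxa1, a pioneer factor for the estrogen receptor (2.41), and the receptor gene Esr1 itself (1.60 ± 0.30, 0.00408). They had less Thbs1 (-5.03 ± 0.21, adjusted p = 9.17e-11), Ltf (-5.02), Igfbp5 (-5.01), Csn1s1 (-4.91) and Kit (-4.63). Luminal progenitor genes were lower, 12 of 19 and 14 adjusted over the list alone (median -2.69; adjusted p = 2.52e-20, and 0.00692 with an estimated correlation). So were milk genes, 8 of 19 and 10 adjusted over the list alone (median -2.03; adjusted p = 1.08e-09, and 0.0318 with an estimated correlation). Hormone-sensing genes were higher, 4 of 14 and 9 adjusted over the list alone (median 1.29; adjusted p = 2.8e-07, and 0.00726 with an estimated correlation). Class I antigen presentation genes were higher, 3 of 8 and 6 adjusted over the list alone, with Tap2 (1.52) and B2m (0.42) having the smallest p (median 0.65; adjusted p = 7.43e-06, and 0.00396 with an estimated correlation). Pgr did not pass (1.82, adjusted p = 0.0952). Elf5 (-3.24, 0.0229) lost its call without Sca1-negative replicates 1 and 2 (0.102, 0.0566) and without Sca1-positive replicates 1, 2 and 3 (0.0641, 0.056, 0.0769). In total 415 genes were higher and 320 lower, and 458 in all without Sca1-positive replicate 3. A fit of only the compared groups called 311 and lost 25 of 50 named genes, among them Esr1 (adjusted p = 0.19), Foxa1 (0.155), Tap2 (0.083) and B2m (0.0691), while Pgr passed (0.0138).

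In mutant mice the Sca1-positive cells had more Il33 (4.10 ± 0.41, adjusted p = 6.64e-06), Msx2 (3.03), the progesterone receptor gene Pgr (2.98, 0.00455), Foxa1 (2.61) and Esr1 (2.14 ± 0.30, 0.000309). They had less Btn1a1 (-3.09), Xdh (-2.98), the EGF receptor gene Egfr (-2.87) and Kit (-2.78). Hormone-sensing genes had 10 of 14 higher, and 11 adjusted over the list alone (median 1.97; adjusted p = 1.52e-15, and 0.000446 with an estimated correlation). Luminal progenitor genes had 10 of 19 lower, and 14 adjusted over the list alone (median -1.77; adjusted p = 6.94e-15, and 0.0153 with an estimated correlation). Milk genes had 7 lower and 1 higher, and 9 and 1 adjusted over the list alone (median -1.11; adjusted p = 4.58e-08, and adjusted p = 0.0512 with an estimated correlation). Basal genes had 4 lower, Egfr and Nrg1 (-2.61) with the smallest p, and 6 adjusted over the list alone (median -0.53; adjusted p = 3.84e-07, and adjusted p = 0.074 with an estimated correlation). Class I genes had 1 higher and 4 adjusted over the list alone (median 0.58; adjusted p = 5.85e-05, and 0.00701 with an estimated correlation). The genotypes shared 158 higher genes (7.51 by chance) and 161 lower genes (5.91 by chance), with no array in common. In total 361 genes were higher and 368 lower. The count was 428 without Sca1-negative replicate 1, 463 and 390 without Sca1-positive replicates 2 and 3, and 319 in a fit of only the compared groups. There 36 of 52 named genes lost their call, among them Kit (adjusted p = 0.0779), Foxa1 (0.0634), Pgr (0.171) and Nrg1 (0.0685).

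**Figure D4:**
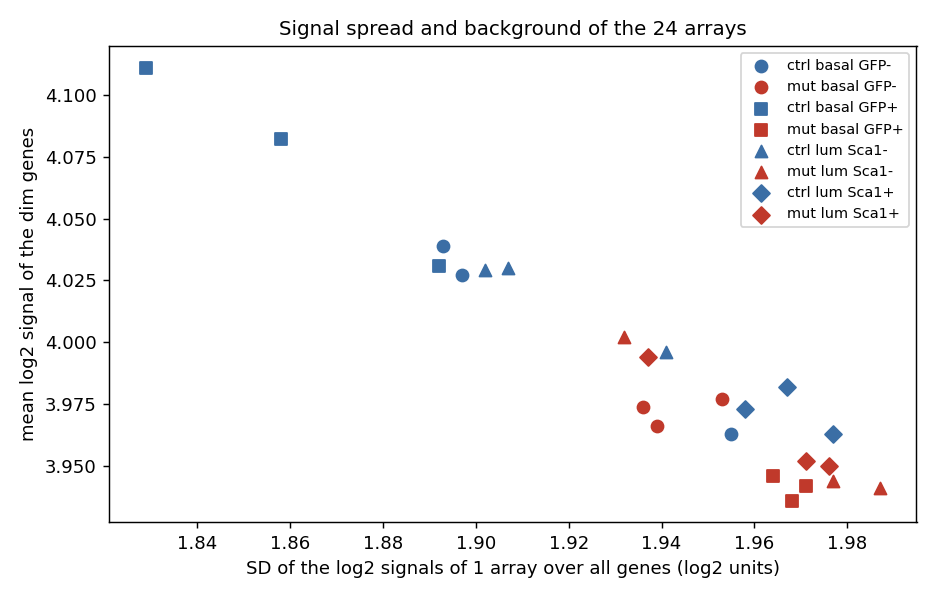
Standard deviation of the log2 signals of each array against the mean of its dim genes, in log2 units, with 1 point per array. Control arrays are blue and mutant arrays red, with 1 marker shape per sorted population. The control basal GFP-positive group has a mean of 1.86 for the standard deviation and 4.08 for dim genes, and the mutant basal GFP-positive group 1.97 and 3.94.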

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

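The 4 tests of carried-over cells were chosen after the result they test was seen, the 2 on keratin and contractile genes after those on abundant genes, and the control basal GFP-negative arrays were taken as a reference after the control basal GFP-positive arrays were seen to stand apart, with the outcome of that test not yet seen. The splits for differences of effects were divided by the labels they keep after their counts were seen.

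Mutant basal GFP-positive cells had 2504 called genes, against 12, 145 and 155 in the other mutant comparisons. The control basal GFP-positive arrays had the narrowest spread of signal of the 8 groups (1.86) and the brightest dim genes (4.08), as a higher background gives. With the control basal GFP-negative arrays as the reference the 1558 lower calls became 185, as a background in those control arrays would produce, so a technical source remains open for most lower calls. Of the 608 genes higher by at least 2-fold 40.5% were called higher again, a share between the bounds set beforehand, so for the higher genes as a set background cannot be told apart from the mutant effect by this test, which also changes the GFP state of the control. Csn2 (5.90, and 5.73 against that reference), Csn1s1 (5.60 and 5.32), Ehf (4.70 and 4.90) and Apod (4.64 and 4.55) were called against either one. A higher background raises low control levels (Csn2 5.16, Ehf 5.29) and would shrink such rises, so the change of reference could hardly decide this. The direction and size of these 4 differences argue against background in the control GFP-positive arrays as the whole of them. A response to mutant PIK3CA, the GFP gate that differs with the genotype, and the carried cells weighed next stay open.

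In mutant basal GFP-positive cells 8 of 19 luminal progenitor and 8 of 19 milk genes were called higher and 1 milk gene lower, and neither list passed with an estimated correlation (adjusted p = 0.134 each, and 0.102 each against control GFP-negative cells). If luminal Sca1-negative cells of the mutant had passed the CD24 and Sca1 gates into the basal gate, 13 risen genes would need a median of 28.2% luminal RNA (19.3 to 52.9% over 3 arrays). These 13 were picked as list members called higher in these same arrays, and members that did not rise were left out. Selection thus adds to their share, and a gap to unselected genes does not by itself weigh against carried cells. The most abundant luminal-high genes gave 16.1% (7.4 to 23.4%), which overlaps and leaves carry-over open. With Sca1-positive cells as the source there was no overlap (78.1% needed, 58.6 to 143.3%, against 9.4%, 6.2 to 15.3%). The 8 luminal keratin and junction genes at least 4-fold higher in the luminal source than in control basal cells gave 3.7% (-2.1 to 6%). The abundant genes had only to be higher there, so these sets follow unequal rules. Cdh1 (24.2%) and Krt8 (10.9%), in the abundant set, lie under the 4-fold limit. Krt18 stood at 10.18 against 9.63 in control, and Krt19 at 6.48 against 6.4. This argues only against carried cells with the average keratin content of that luminal gate at the share the risen genes need, which selection raises. The risen genes need unequal shares of Sca1-negative RNA, from 7.5% (Cd14) and 8.2% (Wap) to 73.7% (Mfge8), 93.6% (Csn3) and 110% (Xdh). Krt5 stood at 11.92 against 11.6 in control, with 8.5 in that luminal gate. For Mfge8, Csn3 and Xdh this argues against carried cells of the gate's average content as the whole of the rise. Over the risen genes as a set, a smaller share of average luminal cells, luminal cells low in keratins, and alveolar gene expression in basal cells of the mutant each stay open. They were not tested apart.

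Basal genes were higher in mutant luminal Sca1-negative cells, where genotype and GFP state go together. Mutant basal GFP-positive cells carried past the CD24 gate are a candidate source: the 5 risen basal genes need a median of 9.4% of their RNA (7.3 to 11.9%), and the most abundant basal-high genes gave 8.9% (5.9 to 10.2%), about the share they need, with no overlap for GFP-negative basal cells as the source (12.3%, 10.5 to 15.5%, against 4.6%, 1.7 to 5.3%). Krt5, Krt14, Krt17 and Sparc stand in both sets, so the 2 shares are not independent. The 5 risen genes were also picked as those called higher in these same arrays, which raises the share they need. Single abundant genes gave from -25.6% (Gas6) to 333.7% (Chil1), a spread that 1 carried share does not give. The 8 contractile genes at least 4-fold higher in mutant basal GFP-positive than in control luminal Sca1-negative cells gave 1% (0.1 to 2.7%). Acta2 stood at 7.60 ± 0.69 in mutant and 5.52 ± 0.22 in control, against 12.11 in mutant basal cells. This argues only against carried basal cells with average contractile content at the share the risen genes need. A smaller share of average basal cells, carried basal cells low in contractile genes, and basal gene expression in luminal cells of the mutant stay open. All 25 basal genes are expressed in this tissue, 4 of them also standing in another list.

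In the other splits of the same arrays, 1 of 10 splits (the real one) called as many genes in each of the 10 pair comparisons, and 10 splits are too few for a share under 0.05. The real count and the highest other were 2504 and 6 for the mutant effect in basal GFP-positive, 12 and 11 in basal GFP-negative, 145 and 3 in luminal Sca1-negative and 155 and 14 in luminal Sca1-positive cells. For GFP-positive against GFP-negative basal cells they were 250 and 63 in control and 500 and 3 in mutant. For luminal against basal cells they were 1994 and 30 in control and 1567 and 1 in mutant, and for Sca1-positive against Sca1-negative cells 735 and 6, and 729 and 2.

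The mutant effect differed between basal GFP-positive and GFP-negative cells in 214 genes (154 with the larger value in GFP-positive cells, 60 with the smaller). This contrast uses the control basal GFP-positive arrays that stand apart, and without their replicate 2 the count was 588. It was 53 in a fit of only the compared groups, where 2 of the 10 genes named next lost their call. With predicted genes left out, the 5 each way with the smallest p were Arhgap24 (4.38), Fndc1 (4.13), Lipk (3.52), Alox12e (3.37) and Dach1 (3.20), and Grik3 (-4.16), Scn7a (-2.52), Arhgap42 (-1.98), Col14a1 (-1.61) and Hdgfl3 (-1.34). Fndc1 differed between genotypes by 4.10 in GFP-positive and -0.03 in GFP-negative cells, and Grik3 by -4.26 and -0.09. Of 100 splits 12 gave as many genes, with a highest other of 1252, but the 11 others each keep or wholly exchange the genotype labels of 1 pair and so hold a full mutant effect. The 75 splits that mix both pairs called at most 9, and the test leaves chance undecided.

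Between luminal Sca1-positive and Sca1-negative cells the mutant effect differed in 32 genes, 16 each way. The count was 60 without mutant Sca1-positive replicate 1. It was 5 in a fit of only the compared groups, where 7 of the 10 genes named next lost their call. Thbs1 (3.53), Apod (3.39), Crabp1 (2.77), Htr4 (2.28) and Galnt15 (1.33) had the larger value in Sca1-positive cells, and Ctsr (-2.94), Cxcl14 (-2.14), Fyb2 (-2.11), Prkaa2 (-1.91) and Nrxn3 (-1.73) the smaller. Thbs1 differed between genotypes by 3.50 in Sca1-positive and -0.03 in Sca1-negative cells, and Apod by 5.62 and 2.23. Of 100 splits 10 gave as many genes, with a highest other of 308, and the 9 others again keep or exchange 1 pair whole (at most 4 genes in the 75 that mix both), so chance is left undecided here too.

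Between luminal Sca1-negative and basal GFP-positive cells the mutant effect differed in 205 genes (76 and 129). Without control basal GFP-positive replicate 2, of the group that stands apart, the count was 402. Amtn (4.53), Cxcl14 (3.14), Scn7a (2.50), Prkaa2 (2.09) and Col14a1 (2.00) had the larger value in luminal cells, and Fndc1 (-3.90), Arhgap24 (-3.39), Lipk (-3.30), Dach1 (-2.59) and Hpse2 (-1.94) the smaller. Amtn differed between genotypes by 4.82 in luminal and 0.29 in basal cells. Of 100 splits 11 gave as many genes, with a highest other of 2535, and the 10 others keep or exchange 1 pair whole (at most 3 genes in the 75 that mix both), which leaves chance undecided.

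Of the 13120 probe sets with several gene symbols or none, 202 were called in mutant against control basal GFP-positive cells (88 higher, 114 lower), 14 in luminal Sca1-negative cells (8 and 6) and 19 in luminal Sca1-positive cells (10 and 9).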

How the results depend on the processing

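The reference of control basal GFP-negative arrays and the fit without the control basal GFP-positive arrays were added after seeing the data. Of 128 counts of called genes under another setting 109 stayed within 1.5 times, and of 96 with 1 array left out 74 did. The cause was not tested unless named.

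A fit of only the compared groups has fewer arrays to estimate the spread from, and uses their own spread, not that pooled over the 8 groups. The groups differ in spread: arrays of a group correlated at a mean of 0.937 in control and 0.977 in mutant basal GFP-positive cells. Where the compared groups vary more than the rest, the pooled spread gives p-values that are too small. Fewer arrays and a larger spread were not told apart as the source of the lower counts. The fit of only the compared groups called 234, 0, 34 and 8 genes for the mutant effect in basal GFP-positive, basal GFP-negative, luminal Sca1-negative and luminal Sca1-positive cells. It called 0 and 191 between GFP-positive and GFP-negative basal cells (control, mutant), 765 between luminal Sca1-negative and basal cells in control, 311 and 319 between the luminal fractions, and 53 and 5 for the differences of the mutant effect within basal and within luminal cells. Where this limma fit called 0, 860 genes (basal GFP-negative) and 1690 (between the basal fractions in control) had an unadjusted p under 0.05. The 860 are a share under 0.05 of the 19937 genes, no more than chance alone gives, and the 1690 a larger one. Quantile normalization gave 1213 genes in basal GFP-positive and 7 in basal GFP-negative cells, and leaving out dim genes 1515 in basal GFP-positive cells. Array weights gave 32 and 788 between the basal fractions in control and mutant and 52 for the luminal difference of effects. The control basal GFP-negative reference gave 641 in mutant basal GFP-positive cells, and the fit without the control basal GFP-positive arrays 6 in basal GFP-negative cells.

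Against the control basal GFP-negative reference Actg2 (-0.23), Myocd (0.0203) and Pik3ca in control luminal Sca1-negative cells (-0.68) turned, the first 2 in mutant basal GFP-positive cells, as did the lists of cell cycle (adjusted p = 0.852) and ribosomal proteins (0.00221, and 0.192 with an estimated correlation) there. Lineage score differences became 0.157, 0.535 and -0.26 with the fixed lists in basal GFP-positive, basal GFP-negative and luminal Sca1-positive cells, and -1.76 with 50 genes in luminal Sca1-negative cells. List tests passed 68 times of 220, 23 times with an estimated correlation, 73 with fry and 54 with quantile normalization. Of 548 pairs of a named gene and a comparison, 511 kept direction and side of the threshold with quantile normalization, 522 with array weights, 536 with the replicate block and 324 in the fit of only the compared groups.

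Without 1 array the counts ran from 1034 to 3979, 9 to 32, 110 to 149 and 103 to 183 for the mutant effects in the order above. They ran from 104 to 1126 and 314 to 440 between the basal fractions, 1450 to 2760 and 1154 to 1280 between the lineages, 458 to 582 and 390 to 703 between the luminal fractions, and 147 to 588, 23 to 60 and 141 to 402 for the differences of effects. The score differences ran from 0.321 to 0.605, 0.094 to 0.33, -1.03 to -0.848 and -0.145 to 0.001.

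The labels name 3 independent sortings but tie no array to 1, so arrays of different populations share only a replicate number. Residuals of arrays with the same number correlated at a mean of 0.037 within a genotype and 0.031 between genotypes. The highest mean for a pair of groups was 0.116, between the mutant luminal fractions. Residuals in a group of 3 sum to 0, so the values for other numbers (-0.019 and -0.016) follow from these and are no separate comparison. A sorting shared by replicate number is not excluded. With the replicate block the counts were 2350, 11, 160 and 164 for the mutant effects, 254 and 517, 2040 and 1585, and 761 and 756 for the pairs, and 210, 35 and 211 for the differences. The block gave score differences of 0.425, 0.233, -0.954 and -0.076, and 65 list calls. Signal near background limits dim genes: a gene under 4.66 has little room to show a lower level, and the size of a difference from such a level is not exact.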

Other observations

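In control mice the Notch ligand gene Dll1 stood at 9.02 ± 0.28 in basal GFP-positive and 4.96 ± 0.17 in luminal Sca1-negative cells (-4.06 ± 0.20, adjusted p = 1.74e-10), Jag2 at 7.03 ± 0.12 and 4.67 ± 0.06 (-2.35 ± 0.31, 3.95e-05) and Jag1 at 7.05 ± 0.30 and 5.22 ± 0.33 (-1.84 ± 0.24, 3.98e-05). In mutant mice Dll1 (-3.35 ± 0.20, adjusted p = 2.3e-09) and Jag2 (-2.30 ± 0.31, 4.82e-05) were lower in luminal cells too, as was Jag1 (-4.23 ± 0.24, 1.1e-09), with 9.80 ± 0.11 in basal and 5.57 ± 0.37 in luminal cells. The 17 Notch pathway genes as a list had an adjusted p of 0.507 in control and 0.0479 in mutant mice, the latter 0.269 with an estimated correlation.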
